A study of Mus musculus with 43 samples.

How the data were processed

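RNA sequencing was available for 43 libraries of sorted mouse bone marrow cells. Per the labels, 5 M JAK2V617F (M, 1000000) whole marrow cells carrying CD45.2 had been given to unconditioned wild-type CD45.1 mice, and untransplanted CD45.1 mice served as controls. The groups were host cells of transplanted mice (CD45.1, n = 7), donor cells from the same 7 mice (CD45.2, n = 7), CD45.1 cells of controls (n = 8), stroma-enriched cells of the same transplanted mice (n = 7) and controls (n = 8), and CD45.1 CD11b-positive cells from other mice, 3 transplanted and 3 controls. The stroma gate removed cells carrying CD45 or a marker of B cells (B220), red cells (Ter119), myeloid cells (CD11b, Ly-6G/Ly-6C), T cells (CD8, CD4) or NK cells (NK1.1). The first 5 groups were taken about 7 months after transplantation and the CD11b cells after 52 weeks. Groups were taken from the sample titles. For the donor library of animal N204 the title gives donor cells and a characteristic gives recipient-derived cells, and its expression lay with the other donor libraries on the first principal component.

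Per the labels' protocols, the CD45-sorted samples were made into strand-specific poly-A libraries, and the stroma samples into low-input libraries sequenced in 2 runs. Per the submitters' processing notes, reads were aligned with STAR 2.7.3a to GRCm39 and assigned to genes with featureCounts of Subread 1.6.2, and RSEM 1.3.3 is listed in addition for the CD11b libraries. The deposited gene counts are whole numbers without normalization. The deposited TPM values sum to 1000000 per library within rounding, and the tool that made them is not stated. The annotation, the strand setting of the counting and the merging of the 2 stroma runs are not stated either. Another deposited table was not used. Counts cover 56941 gene identifiers, of which 51948 matched a symbol in the reference gene table and 131 shared one with another identifier. Reads of near-identical copies can be divided between genes in such counting, which leaves the values of single haemoglobin, immunoglobulin constant, T-cell-receptor constant, Apol11 and pseudogene entries uncertain. Gene counts cannot tell the mutant from the normal Jak2 allele.

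Main tests used edgeR 4.0.16 in R 4.3.3: genes were kept by filterByExpr, scaled by TMM and tested with the quasi-likelihood F-test, with sex as a covariate except among the all-male CD11b samples. Each fit held the 2 groups compared. P-values were adjusted by the Benjamini-Hochberg method, and a gene passed at an adjusted p below 0.05. Log2 fold changes and their standard errors come from these fits, and group levels are TMM-scaled CPM (counts scaled to a library of 1000000) given as mean ± SD. The test of 39 gene lists used camera of limma 3.58.1 with a preset correlation between genes of 0.01 on voom values, adjusted over the 39 lists, beside camera with an estimated correlation and fry. With the estimated correlation 1 list passed in host cells, the macrophage genes, and 0 lists passed in each of the other 4 main comparisons. Sex-by-transplant interactions were tested in host cells and stroma, and slopes on log2 of the final blood chimerism in host, donor and stroma samples.

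The groups, tests, gene lists, alternatives and rule for named genes were chosen before the data were examined, apart from 4 alternatives and the tests of explanations, which were chosen after seeing the data. Named genes were the up to 10 highest and 10 lowest log2 fold changes among genes that passed with a mean log2 CPM of at least 2, passing over unnamed gene models and antigen-receptor segments. Where fewer than 5 passed in a direction, the 5 with the smallest p were named as not passed. Up to 4 members with the smallest p of each described list, genes that passed in the same direction in at least 3 of the comparisons with controls, and a fixed set of genes of interest were also named. The fixed set was Jak2, Ptprc, S100a8, S100a9, Il1b, Lcn2, Pf4, Socs2, Cish and Pim1, with Cxcl12, Kitl, Lepr, Angpt1, Col1a1 and Tgfb1 in stroma.

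All 43 libraries matched their labelled sex by Xist and Y-linked genes. Donor and host libraries of 1 animal deviated together from their group means in all 7 animals, with correlations across genes of 0.174 to 0.6. The 5 pairs of transplanted and control mice killed on the same day, per the labels, gave correlations of 0.238 to 0.292 for host cells, 0.162 to 0.283 for donor cells and 0.052 to 0.526 for stroma. The animal and the day were therefore also fitted as blocks. Other alternatives were DESeq2 1.42.0, limma-voom, other scalings, no filter and a stricter filter on low counts, limma-trend on TPM with pseudocounts of 1 and 0.1, a fold-change minimum, each sex alone, and leaving out each library in turn. Each fit was tested on simulated counts with 200 genes changed by a log2 value of 1 or 2, which for the slopes is the change per doubling of chimerism. Of the genes changed by 1, the fit recovered 95% for host against control, 94% for donor against control, 92% for donor against host, 37% for stroma and 63% for CD11b. Of those changed by 2 it recovered 100%, 100%, 100%, 91% and 79% in the same order. Transcript 5' GC content came from a reference annotation of another genome build than the authors' and was matched by gene identifier alone. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.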

Results

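The expression of 56941 genes was counted in 43 libraries of sorted marrow cells from transplanted and untransplanted mice. Library totals (M, 1000000) were 16.3 to 19.05 M counts in the 7 host libraries, 16.34 to 19.68 M in the 7 donor libraries and 15.71 to 18.56 M in the 8 CD45.1 control libraries. They were 41.21 to 63.97 M in the 7 stroma libraries of transplanted mice, 50.73 to 143.23 M in the 8 of controls, 32.48 to 44.85 M in the 3 CD11b libraries of transplanted mice and 35.53 to 42.98 M in the 3 of controls. The final blood chimerism, for which the labels give no unit, ran from 0.63 to 5.99 in the 7 transplanted mice with host, donor and stroma libraries. The CD11b mice had no value. Controls had values from 0 to 0.00392, and those of N093 and N002 differ between their CD45.1 and stroma libraries. Jak2 itself was read at 204.7 ± 16.5 CPM in host cells (SD, n = 7) and 210.7 ± 16.7 in controls (n = 8).

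The comparison of host cells with control cells addressed how wild-type marrow cells differ when they share the marrow with transplanted JAK2V617F cells. An effect of the mutant cells was not separated from one of transplantation, since no mice were given normal marrow. Of 14 macrophage genes 11 were higher and of 24 B-lineage genes 23 lower, and of these lists the macrophage one alone passed with an estimated correlation. C1qa, a chain of complement C1q made by macrophages, stood at 11.6 ± 4.61 CPM in host cells (SD, n = 7) and 0.647 ± 0.194 in controls (n = 8), a log2 fold change of 4.08 ± 0.25 (SE; edgeR adjusted p = 5.19e-08). Vcan, the matrix proteoglycan versican that inflammatory monocytes express, rose from 21.8 ± 5.55 to 131.6 ± 38.0 CPM (log2 2.55, edgeR adjusted p = 5.19e-08). Saa3, an acute-phase serum amyloid A gene, rose from 1.58 ± 0.502 to 13.1 ± 4.91 CPM, and Lipg, endothelial lipase, from 1.43 ± 0.743 to 15.0 ± 10.7 CPM. In the other direction the B-cell surface gene Ms4a1, which encodes CD20, fell from 38.8 ± 14.7 to 12.6 ± 5.58 CPM (log2 -1.71, edgeR adjusted p = 3.27e-04).

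Of 14073 genes tested, 2312 passed, 1211 higher and 1101 lower, and 86 and 200 of these differed at least 2-fold. The 10 highest log2 fold changes under the naming rule included C1qc 4.16, C1qa, C1qb 3.68, Lipg 3.48, Saa3 3.02, the myeloid receptor gene Cd300e 2.88, the integrin gene Itgad 2.82, Vcan and F11r 1.86. The 10 lowest were Car1 -2.34, Fcer2a -1.81, Ms4a1, Tnfrsf13c -1.66, Col5a3 -1.65, Srpk3 -1.64, Reln -1.61, Fcmr -1.61, Cacna1i -1.60 and Blk -1.60. Among them Fcer2a, Tnfrsf13c, Fcmr and Blk encode B-cell receptors or signalling proteins. On TPM plus 1 Reln was at -0.75 (limma adjusted p = 0.0522). Car1, the carbonic anhydrase of young erythroid cells, stood at 2.64 ± 0.985 CPM in host cells and 13.2 ± 3.49 in controls.

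Of 14 macrophage genes measured, 11 rose and none fell (12 adjusted over the list alone), with a median log2 of 0.73 and a camera adjusted p of 4.24e-12 (adjusted p = 0.033 with an estimated correlation). Cd5l, a secreted macrophage protein gene, was at log2 4.70. Of 18 monocyte genes 7 rose and 1 fell (10 and 2 adjusted over the list alone; median 0.27, camera adjusted p = 0.0036, adjusted p = 0.546 with an estimated correlation). The risen ones included Ccr2 at 0.81, the receptor that draws monocytes to inflamed tissue, Tgfbi at 0.55, Ms4a6c at 0.51 and Ctss at 0.44, and Nr4a1 fell by 0.38. Of 11 neutrophil primary-granule genes, made at the promyelocyte stage, 6 rose (9 adjusted over the list alone), such as Ctsc at 0.56, Prtn3 at 0.56 and Ctsg at 0.42. Their median was 0.33 with a camera adjusted p of 1.52e-04, and adjusted p = 0.457 with an estimated correlation. None of 20 mature neutrophil genes passed, over all genes or adjusted over the list alone. All 20 lay below 0, with a median of -0.29 and a camera adjusted p of 0.00207 (adjusted p = 0.644 with an estimated correlation, and 0.373 with the day of euthanasia as a block). The alarmin genes S100a8 at -0.32 and S100a9 at -0.36, and Il1b at -0.35 and Lcn2 at -0.29, did not pass, with edgeR adjusted p of 0.296, 0.242, 0.31 and 0.322.

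Of 24 B-lineage genes 23 fell (24 adjusted over the list alone; median -1.29, camera adjusted p = 6.91e-21, adjusted p = 0.349 with an estimated correlation). Spib fell by 1.41, Cd79b by 1.31 and Blnk by 0.98. Immunoglobulin genes took 0.273 ± 0.0802% of counts in host libraries and 0.442 ± 0.0992% in controls. Of 10 MHC class II genes 4 fell, the same number adjusted over the list alone, among them H2-Ob at -1.30 and H2-DMb2 at -1.17, both antigen-loading genes of B cells (camera adjusted p = 0.014, adjusted p = 0.633 with an estimated correlation). Of 26 T and NK cell genes 2 fell (1 adjusted over the list alone), among them Gzma at -0.96 (median -0.25, camera adjusted p = 0.014, adjusted p = 0.644 with an estimated correlation). Of 22 DNA replication genes 6 rose (11 adjusted over the list alone), such as Mcm5 at 0.28 and Cdc45 at 0.26 (median 0.19, camera adjusted p = 2.07e-05, adjusted p = 0.457 with an estimated correlation). Of 24 JAK-STAT target and feedback genes 1 rose and 7 fell, also adjusted over the list alone (median -0.11, camera adjusted p = 0.021, adjusted p = 0.565 with an estimated correlation). Il2ra fell by 0.99 and the feedback inhibitor gene Socs2 by 0.78, from 4.59 ± 0.926 to 2.66 ± 0.85 CPM, and Cdkn1a was the one that rose, by 0.28. Cish at 0.11, Pim1 at -0.01, Ptprc at -0.18, Pf4 at 0.06 and Jak2 at -0.04 did not pass. The number of genes that passed was 1527 without host library N014, and 479 and 121 in males and females alone.

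**Figure D1:**
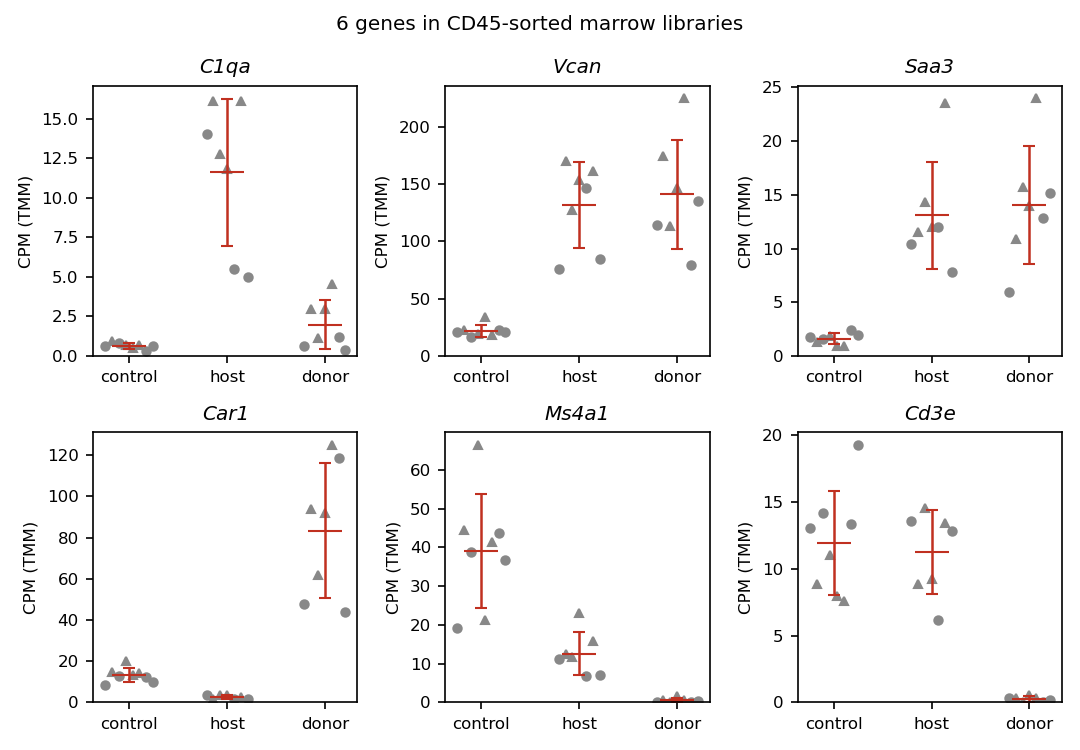
Level in CPM of 6 genes in each control (n = 8), host (n = 7) and donor (n = 7) library, circles for females and triangles for males, with red lines at the mean ± 1 SD, the lower one limited at 0. C1qa was higher in host than in donor cells, Car1 lower in host and higher in donor cells than in controls, and Ms4a1 and Cd3e near 0 in donor cells.

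The comparison of donor cells with control cells addressed how the transplanted JAK2V617F cells differ from normal marrow. Donor cells also differ from controls in CD45 type and in having been transplanted. No mice were given normal marrow, so an effect of the mutation was not separated from these. Donor cells had little lymphoid expression, and Car1 and Pklr were among the most raised genes. Ms4a1 stood at 0.544 ± 0.547 CPM in donor cells (SD, n = 7) and 38.8 ± 14.7 in controls (n = 8), and Jchain, the joining chain of secreted antibodies, at 2.25 ± 1.42 and 176 ± 33.4 CPM (edgeR adjusted p = 1.44e-10). Car1 rose from 13.2 ± 3.48 to 82.7 ± 32.5 CPM (log2 2.63 ± 0.20 SE, edgeR adjusted p = 1.91e-08) and Pklr, the pyruvate kinase gene of red cells, from 0.876 ± 0.391 to 8.89 ± 4.54 CPM (log2 3.33). Jak2 itself was lower, at 172.8 ± 15.0 against 210.9 ± 18.1 CPM (log2 -0.29, edgeR adjusted p = 0.00294).

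Of 13906 genes tested, 6360 passed, 3163 higher and 3197 lower, with 174 and 1052 differing at least 2-fold. Beside Pklr and Car1, the highest changes were Lipg 3.69, Saa3 3.12, the tight-junction gene Tjp1 3.02, Atp1b2, Vcan 2.64, Add2 2.44, Ces2g 2.23 and Myh10 2.20. On TPM plus 1 Myh10 was at 0.14 and did not pass. Lipg, Saa3 and Vcan were thus among the highest of both donor and host cells. The lowest were Ighg3 -9.52, Dtx1 -6.41, Jchain -6.29, Ms4a1 -6.25, Iglc1 -6.12, Igkc -6.10, Cacna1i -6.07, Fcmr -6.04, Tdrp -6.04 and Fcer2a -5.93. Ighg3 had no counts in 5 of 7 donor libraries, and its value ran from -14.02 to -4.88 over the alternatives.

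All 24 B-lineage genes fell, also adjusted over the list alone (median -4.61, camera adjusted p = 4.01e-19, adjusted p = 0.19 with an estimated correlation), among them Blk at -5.52 and Cd22 at -4.35. Of 26 T and NK cell genes 25 fell, also adjusted over the list alone (median -3.59, camera adjusted p = 4.01e-19, adjusted p = 0.19 with an estimated correlation), such as the T-cell-receptor complex gene Cd3e at -5.48 and Lck at -4.02. Of 17 plasma cell genes 13 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 1.4e-05, adjusted p = 0.19 with an estimated correlation). Of 14 dendritic cell genes 10 fell (12 adjusted over the list alone), such as Irf4 at -4.52 and Siglech at -2.32 (camera adjusted p = 3.49e-06, adjusted p = 0.226 with an estimated correlation). Of 10 MHC class II genes 9 fell, also adjusted over the list alone (median -1.43, camera adjusted p = 8.09e-06, adjusted p = 0.383 with an estimated correlation). Immunoglobulin genes took 0.0158 ± 0.00428% of counts in donor libraries.

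Of 24 erythroid genes 12 rose and 4 fell (13 and 5 adjusted over the list alone; median 0.57, camera adjusted p = 0.0338, adjusted p = 0.676 with an estimated correlation and 0.488 with the day of euthanasia as a block). The risen ones included the transcription factor genes Klf1 at 2.24 and Gata1 at 2.01 and Ermap at 1.94. Among the fallen were the adult globin genes Hba-a1 at -1.69 and Hbb-bs at -1.54, the end products of red-cell maturation, which were picked out after their values were seen. Of 11 primary-granule genes 10 rose, also adjusted over the list alone (median 0.57, camera adjusted p = 2.55e-05, adjusted p = 0.226 with an estimated correlation), with Prtn3 at 0.92 and Ctsg at 0.75. Of 22 DNA replication genes 20 rose, also adjusted over the list alone, such as Cdc45 at 0.46 (camera adjusted p = 1.09e-08, adjusted p = 0.19 with an estimated correlation). Of 22 mitotic genes 16 rose and 1 fell (17 and 1 adjusted over the list alone), such as Aurka at 0.48 (camera adjusted p = 4.2e-05, adjusted p = 0.462 with an estimated correlation). Of 76 oxidative phosphorylation genes 53 rose and 1 fell (55 and 1 adjusted over the list alone; median 0.29, camera adjusted p = 3.2e-11, adjusted p = 0.447 with an estimated correlation).

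Of 24 JAK-STAT target and feedback genes 2 rose and 11 fell in donor cells (2 and 12 adjusted over the list alone; median -0.22, camera adjusted p = 0.00475, adjusted p = 0.447 with an estimated correlation). The fallen ones included Il2ra at -4.04, which lymphocytes express, Socs2 at -1.45, Socs1 at -1.42 and Pim2 at -1.02. Cish, a STAT5 target, rose by 0.47 (edgeR adjusted p = 0.00307), and Pim1 at -0.17 did not pass. Ptprc fell by 0.43, and S100a8 at -0.17, S100a9 at -0.22, Il1b at -0.43, Lcn2 at -0.12 and Pf4 at -0.01 did not pass. In males alone 3027 genes passed.

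Donor and host cells of the same 7 animals were compared, transplanted mutant cells carrying CD45.2 against resident wild-type cells carrying CD45.1. The mutation, the CD45 type and the transplantation were not separated. Car1 stood at 83.6 ± 32.8 CPM in donor and 2.67 ± 1.01 in host cells (SD, n = 7 each; log2 4.96 ± 0.29 SE, edgeR adjusted p = 3.61e-08) and Pklr at 8.98 ± 4.58 and 0.192 ± 0.132 CPM (log2 5.49). The T-cell gene Cd3e was at 0.257 ± 0.203 CPM in donor and 11.4 ± 3.15 in host cells (log2 -5.47, edgeR adjusted p = 5.3e-08). The C1q genes that rose in host cells were lower in donor cells, C1qc by a log2 of -2.96, C1qa of -2.70 and C1qb of -2.47. Jak2 was lower in donor cells (log2 -0.25, edgeR adjusted p = 0.0178) and Cish higher (0.37, edgeR adjusted p = 0.00341).

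Of 13662 genes tested, 1928 passed, 570 higher in donor cells and 1358 lower, with 71 and 625 differing at least 2-fold. With the animal as a block 4605 passed, 2078 higher and 2527 lower, and all 1928 were among them. After Pklr and Car1 the highest were Atp1b2 3.72, Myh10 3.51, Ces2g 2.84, Add2 2.83, Ermap 2.55, the water channel gene Aqp1 2.34, Tjp1 2.31 and Abcb4 2.22. On TPM plus 1 Myh10 was at 0.40 and did not pass. The lowest were Ighg3 -7.43, Cd3e, Jchain -5.33, Igkc -5.32, Trbc2 -5.20, Igha -5.19, Iglc1 -5.15, Dtx1 -5.08, Cd3g -4.98 and Iglc2 -4.93, with Ighg3 from -9.94 to -3.73 over the alternatives.

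Of 24 erythroid genes 10 were higher in donor cells and none lower (10 and 4 adjusted over the list alone; median 0.62, camera adjusted p = 1.57e-04, adjusted p = 0.494 with an estimated correlation), such as Tspo2 at 2.24 and Gata1 at 2.12. Lower in donor cells were 22 of 23 B-lineage genes (camera adjusted p = 5.23e-27, adjusted p = 0.122 with an estimated correlation), 25 of 26 T and NK cell genes (5.1e-33, adjusted p = 0.0547 with an estimated correlation) and 13 of 17 plasma cell genes (4.65e-12, adjusted p = 0.0547 with an estimated correlation), with the same counts adjusted over the list alone. Of 14 macrophage genes 8 were lower (9 adjusted over the list alone; median -0.42, camera adjusted p = 2.98e-05, adjusted p = 0.171 with an estimated correlation), and of 18 monocyte genes 6 were lower, such as Ctss at -0.35 (8 adjusted over the list alone; camera adjusted p = 5.63e-04, adjusted p = 0.207 with an estimated correlation). Of 10 MHC class II genes 9 were lower (10 adjusted over the list alone; median -1.05, camera adjusted p = 1.02e-09, adjusted p = 0.13 with an estimated correlation). Of 30 type I interferon-stimulated genes 8 were lower, such as Oasl1 at -0.74 (11 adjusted over the list alone; camera adjusted p = 0.00129, adjusted p = 0.494 with an estimated correlation). Of 22 DNA replication genes 14 were higher, such as Mcm4 at 0.21 (18 adjusted over the list alone; camera adjusted p = 4.11e-11, adjusted p = 0.142 with an estimated correlation). These list tests left out the animal. With the animal as a block the NF-kB inflammatory (camera adjusted p = 0.0289), secondary-granule (0.00932) and glycolysis and hypoxia genes (0.0369) passed in addition. The interferon-gamma response (0.0502) and adipocyte genes (0.0521) then no longer passed.

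Without the block Socs2 at -0.67, Ptprc at -0.24 and Pim1 at -0.16 did not pass, and with the animal as a block these 3 genes did, as did the primary-granule genes Elane at 0.31 and Ctsg at 0.34. S100a8 at 0.16, S100a9 at 0.16, Il1b at -0.06, Lcn2 at 0.18, Vcan at 0.09 and Saa3 at 0.10 did not pass. In males and females alone 1136 and 450 genes passed.

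The calls of the host and donor comparisons overlapped among 13822 genes tested in both: 1015 rose in both (270.9 by independent draws), 1037 fell in both (252.7) and 21 went in opposite directions. Both comparisons share the 8 control libraries. When the controls were split 4 and 4, the median over 36 splits was 787 genes with the same direction, against 2052 with all controls. The medians over these splits were 1032 genes called in host and 4800 in donor cells. Those that rose in both had a median of 313 (76.95 by independent draws) and those that fell in both one of 458 (91.15). The covariance of the log2 fold changes across genes, which are not independent replicates, was 0.225 with all controls and 0.0116 in simulated unchanged groups, where the correlation was 0.464 against 0.654 observed. The simulation shares the controls alone, while host and donor libraries come from the same 7 animals and deviated from their group means together in all 7 (r of 0.174 to 0.6), which it leaves out. Among the 21 were the erythroid-expressed genes Pklr, Car1 and Aqp1, lower in host and higher in donor cells than in controls, and Fabp4, at 2.34 in host and -0.98 in donor cells.

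**Figure D2:**
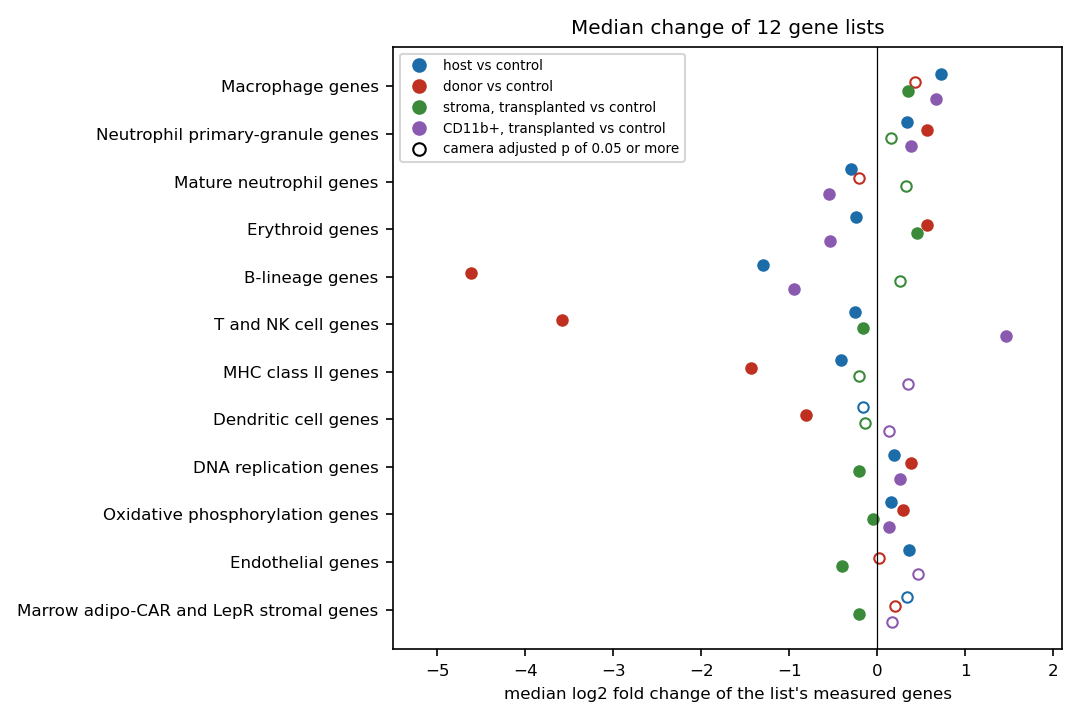
Median log2 fold change of the measured genes of 12 lists in 4 comparisons with control libraries, filled where the camera adjusted p with a preset correlation was below 0.05 and open otherwise. B-lineage genes had medians of -1.29 in host and -4.61 in donor cells, and macrophage genes of 0.73 in host cells.

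The stroma comparison asked how the non-haematopoietic compartment differs in marrow that holds the JAK2V617F clone. Of 24 erythroid genes 9 were higher, as were the C1q genes, and a set of genes including Igfbp7 was lower. Hbb-bs, adult beta-globin, stood at 4101 ± 2829 CPM in transplanted mice (SD, n = 7) and 399.3 ± 185.5 in controls (n = 8; log2 3.33 ± 0.42 SE, edgeR adjusted p = 7.93e-04), and Alas2, which starts haem synthesis in erythroid cells, at 202.9 ± 161 and 17.1 ± 7.49 CPM. C1qb rose from 1.32 ± 0.839 to 13.5 ± 7.35 CPM (edgeR adjusted p = 2.86e-04). Igfbp7, an insulin-like growth factor binding protein secreted by stromal and endothelial cells, fell from 370.9 ± 207.5 to 64.0 ± 28.1 CPM (log2 -2.58, edgeR adjusted p = 0.00211). The niche chemokine gene Cxcl12 stood at 2012 ± 881 and 2689 ± 1627 CPM and did not pass (log2 -0.41, edgeR adjusted p = 0.939).

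Of 26191 genes tested, 391 passed, 122 of them higher and the rest lower, with 108 higher and 181 lower at least 2-fold. Without library N032, which stands apart in its share of ribosomal protein genes, 593 passed. With the day of euthanasia as a block on the 5 same-day pairs 250 passed, 101 higher and 149 lower, and 205 of them were among the 391. The highest were Tcrg-C1 6.75, the ribosome-linked nuclease gene Slfn14 6.06, Tmcc2 5.51, Apol11b 4.23, Alas2 3.50, C1qb 3.36, Hbb-bs, Slc4a1 3.31, Fhdc1 3.24 and Apol11a 3.20. Tcrg-C1, a gamma-delta T-cell-receptor constant gene, was at 13.7 ± 25.1 CPM against 0.0799 ± 0.0866, with 70.0 CPM in library N032 and at most 12.1 in the others. Slfn14 was at 80.1 ± 69.6 against 1.07 ± 0.499 CPM. The lowest included Nrtn -3.21, Igfbp7, Ccdc3 -2.53, the Wnt receptor gene Fzd9 -2.52, Rab5if -2.44, Trir -2.40, Ppp1r35 -2.35, Grasp -2.32 and Glrx5 -2.22. Nrtn, a neurotrophic factor gene, stood at 3.03 ± 3.27 against 19.6 ± 12.8 CPM. The lower genes had a median 5' GC content of 66.4%, and genes that did not pass one of 53.8%.

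Of 24 erythroid genes 9 rose (10 adjusted over the list alone; median 0.45, camera adjusted p = 3.1e-07, adjusted p = 0.875 with an estimated correlation). They included Alas2, Hbb-bs, Slc4a1, Hba-a2 at 3.12, Hbb-bt at 3.10, Trim10 at 3.06, Hba-a1 and Epb42 at 2.06. Gata1 at -0.09, Klf1 at -0.36 and Epor at -0.04 did not pass. Haemoglobin genes took 0.732 ± 0.501% of counts in transplanted mice, with a range of 0.202 to 1.65, and 0.0859 ± 0.0391% in controls. Of 17 macrophage genes 3 rose, C1qb, C1qa at 3.07 and C1qc at 2.56 (4 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.0122, adjusted p = 0.875 with an estimated correlation). None of 24 megakaryocyte and platelet genes passed over all genes and 3 did adjusted over the list alone. All 24 lay above 0 (median 0.76, camera adjusted p = 1.86e-06, adjusted p = 0.875 with an estimated correlation), and with the day as a block the genes that passed included Itga2b at 1.18 and Pf4 at 0.88.

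Of 24 endothelial genes 2 fell (4 adjusted over the list alone; median -0.40, camera adjusted p = 6.06e-07, adjusted p = 0.875 with an estimated correlation): Gpihbp1 at -1.75, which anchors lipoprotein lipase to capillaries, and Ramp2 at -1.33, part of the adrenomedullin receptor. None of 24 marrow stromal genes of the adipo-CAR and LepR type passed, over all genes or adjusted over the list alone (median -0.21, camera adjusted p = 0.00475, adjusted p = 0.875 with an estimated correlation), nor any of 19 niche factor genes (median -0.14, camera adjusted p = 0.045, adjusted p = 0.875 with an estimated correlation and 0.0522 with the day as a block). Kitl at -0.27, Lepr at -0.29, Angpt1 at 0.04, Col1a1 at -0.25 and Tgfb1 at -0.12 did not pass. Of 31 type I interferon-stimulated genes Rsad2 at 2.68 and Isg15 at 1.39 rose (camera adjusted p = 0.155, adjusted p = 0.875 with an estimated correlation, and with a preset correlation 1.08e-04 with the day as a block). Jak2 at 0.11, Cish at 0.89, Pim1 at 0.68, Ptprc at 0.27 and S100a8 at 0.31 did not pass. In females alone edgeR called 0 genes, with 1365 at an unadjusted p below 0.05, and in males 125. DESeq2 called 741 genes and limma-voom 705 in all mice.

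**Figure D3:**
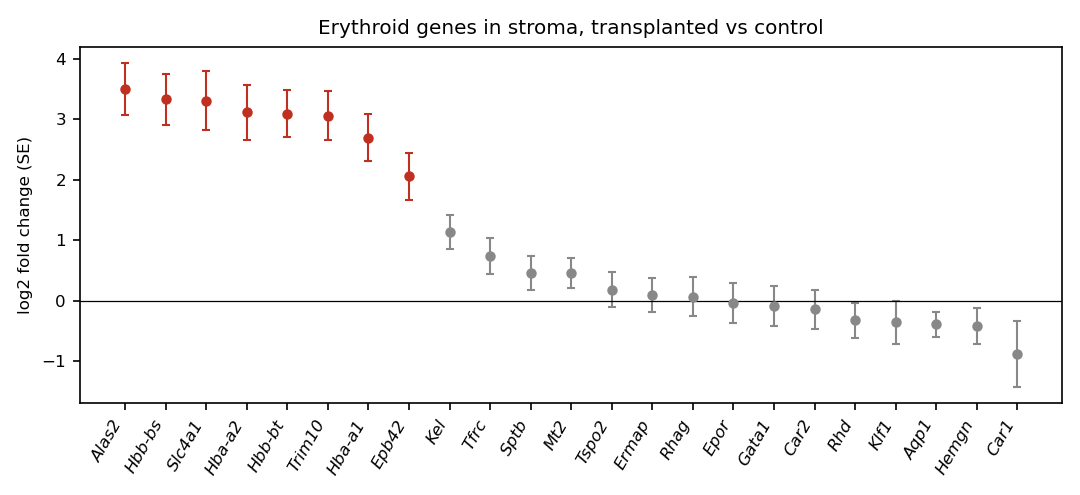
Log2 fold change ± 1 SE of 23 of the 24 erythroid genes in stroma of transplanted mice (n = 7) against controls (n = 8), red where the edgeR adjusted p was below 0.05. The 9 of the 24 genes that rose had a median of 3.10.

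In the 6 CD11b libraries, from other mice at a later time, no gene passed: edgeR called 0 of 15257 genes, with 2506 at an unadjusted p below 0.05 and a smallest adjusted p of 0.0886, while DESeq2 called 333 (218 higher, 115 lower). The higher genes with the smallest p were Cadm1 at 4.11, Shtn1 at 2.07, Ifi30 at 0.84, Abca1 at 2.43 and Asb2 at 3.44, and the lower ones Amer2, Fgl2 at -0.50, Col5a1 at -0.69, Gpcpd1 at -0.46 and Hmgb1-ps8 at -0.60. C1qa was at 2.99 and Saa3 at 9.25, each with an edgeR adjusted p of 0.27. Over the alternatives C1qa ran from 2.36 to 3.46 and Saa3 from 4.70 to 10.30. Jak2 at -0.02, S100a8 at -0.39, S100a9 at -0.40, Il1b at -0.67, Lcn2 at -0.26, Socs2 at 1.54, Cish at -0.11 and Pim1 at -0.13 did not pass. By camera with the preset correlation 15 lists passed, and with an estimated one 0 lists did. Of 11 primary-granule genes 0 passed over all genes and 8 adjusted over the list alone (median 0.39, camera adjusted p = 1.54e-05, adjusted p = 0.735 with an estimated correlation). Of 86 ribosomal protein genes 0 passed and 64 adjusted over the list alone (median 0.34, camera adjusted p = 1.26e-23, adjusted p = 0.735 with an estimated correlation). Of 16 macrophage genes 0 passed and 7 adjusted over the list alone (median 0.67, camera adjusted p = 0.00503, adjusted p = 0.735 with an estimated correlation). The medians of the mature neutrophil and B-lineage genes were -0.54 and -0.95 (camera adjusted p = 5.81e-09 and 2.42e-06, adjusted p = 0.735 with an estimated correlation for both). Without transplanted library N187 28 genes passed, and without N129 Amer2, Cadm1 and Saa3 did.

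Across 13364 genes, which are not independent replicates, the log2 fold changes of CD11b cells and of host cells correlated with r = 0.417, and 1853 of 2179 genes called in host cells had the same sign. These comparisons share no mice. Among the other splits of the CD11b libraries the largest absolute correlation was 0.388, and 10 splits are too few for a share below 0.05. Host cells and stroma of the same mice correlated with r = 0.0735 across 13719 genes, which turned to -0.052 at a mean log2 CPM of at least 4 (Spearman rho = -0.0318 and 47.97% with the same sign over all), and 53 genes were called in both, against 54.6 by independent draws: 19 rose in both (7.7 by independent draws), 12 fell in both (18.8) and the others went in opposite directions. Among genes at a mean log2 CPM of at least 4 in host cells and in stroma, 2 rose in both (4 by independent draws) and 8 fell in both (10.1). Over the comparisons with controls, 11 genes rose and 11 fell in each of host, donor and stroma, and with the day of euthanasia as a block 7 and 3 of these passed in all 3. No chance value was computed for these 22, whose comparisons share controls or mice. Saa3 was at 3.02, 3.12 and 2.77, Ms4a6d, of a gene family expressed in monocytes, at 1.79, 1.58 and 2.05, and C1qa, C1qb and C1qc rose in all 3, though in donor cells not on TPM plus 1 or plus 0.1, nor in females alone (log2 0.26, 0.37 and 0.33). In stroma, whether the rises of the C1q genes and Ms4a6d came from macrophages or monocytes left in the sort was not tested. Cln8 also rose in all 3, and the Notch target gene Hes1 fell at -0.67, -1.85 and -1.78, as did Ypel3, Chst10 and Amigo2. In CD11b cells Hes1 was at 2.40, Ypel3 at -0.42, Chst10 at -0.40 and Amigo2 at -0.52, and none of them passed. Among the 12 that did not pass everywhere with the day as a block, Cln8 (log2 0.86 with the block), Fam208a (-0.45), Cbx7 (-0.82), Oas1g (1.202), Eif2ak3 (-0.77), Stk11 (-1.12) and Tcf3 (-1.48) missed in stroma and Chst10 (-1.06), Cdkn1c (-0.56) and Tdp2 (-0.18) in host cells. Trib3 missed in host cells (0.61) and stroma (1.45), and Eif2ak1 in host (0.18) and donor cells (0.17). The block was fitted on 5 pairs, and each value kept its direction.

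The response of host cells to the transplant did not pass a test of difference between sexes: edgeR called 0 genes for the interaction in host cells (425 at an unadjusted p below 0.05, DESeq2 0) and 0 in stroma (745, DESeq2 0). Slopes on chimerism gave 0 genes in host cells (538 at an unadjusted p below 0.05, DESeq2 3), 0 in donor cells (242, DESeq2 0) and 0 in stroma (680, DESeq2 17). On simulated counts the interaction recovered 58% of genes changed by a log2 of 1 and 94% of those changed by 2 in host cells, and 0% and 25% in stroma. The slopes recovered 100% at both sizes in host and in donor cells, and 57% and 100% in stroma. The slope sizes were log2 changes per doubling of chimerism, which ran from 0.63 to 5.99, several doublings. Slopes with a change of 1 or 2 over that whole range were not simulated.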

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

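All tests of explanations in this part were chosen after the results were seen, while the counts over other splits of the samples and the test for a library far from the others were planned.

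The first pattern is the rise of the 10 most raised genes in host cells of transplanted mice, among them C1qa, C1qb, C1qc, Lipg, Saa3, Cd300e, Itgad, Vcan and F11r. Donor cells carried into the host sort are argued against, since the C1q genes were lower in donor than in host cells (median log2 -2.70) and the other 7 genes would need a donor share of at least 83.0% of the host libraries, while 25 T and NK cell genes left room for 58.5% at most in any host library and 13.8% in the median one. Mean Car1 and Pklr levels in host libraries, both picked after their values were seen, were 3.17% and 2.13% of those in donor libraries, a closer limit on the average share. A smaller share of B cells that raised all other cells alike is argued against by a score difference. The score of 11 macrophage genes, none of them among the 10, minus that of mature neutrophil genes differed by 1.14 log2 between groups (exact two-sided permutation p = 0.00109 over 6435 splits, which ignored sex and day). Both lists had been tested in this comparison before, so the score in part restates those results. A day effect is argued against by the 10 of 10 genes that still passed with the day of euthanasia as a block, at a log2 of 1.83 or more. The pattern may therefore be biological, as a hypothesis found and tested on the same data: more macrophages and monocytes in the sort, or more expression in each, were not separated. No mice were given normal marrow, so a response to the mutant cells and one to transplantation were not separated either.

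The second pattern is the rise of 9 erythroid genes in stroma of transplanted mice, at a median log2 of 3.10, with haemoglobin genes at 0.732% of counts and 0.0859% in controls. More erythroid progenitors of all stages are argued against, since the 12 erythroid genes that were higher in donor than in control cells, a choice that uses no stroma value, had a median of -0.065 in stroma (SD 0.42, against 0.51 for the 9). RNA of late red cells from 1 source needs globin and other raised genes to move together, and across the 7 transplanted libraries the mean of 4 globin genes and that of 5 other genes gave Pearson r = 0.958 (exact permutation p = 0.00139), Spearman rho = 0.929 (exact permutation p = 0.00675) and r = 0.923 without the 2 libraries farthest from the median. Late red cells or their RNA are thus a candidate source, although the gate removes Ter119-positive cells and the marrow had gone through red-cell lysis. Whether the transplant raised the number of such cells or their passage through the sort was not tested.

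The third pattern is the 5' GC content of the genes that fell in stroma: 48.5% of 266 were among the 2530 tested genes with the highest values (66.8% GC or more), against 5.31% of the 113 that rose. A smooth GC trend between groups as the whole cause is argued against, since 69.5% of the lower genes still passed with that trend removed per library, and their median went from -1.19 to -1.08 (median SE 0.22), with Igfbp7 at -2.39 and Nrtn at -3.02. Libraries N032 and N093 are argued against, since 86.2% of the lower genes still passed without both. Library preparation that followed the groups cannot be told apart from the transplant: the level of those 2530 genes relative to other genes differed by -0.24 log2 (exact two-sided permutation p = 0.0129, SDs of 0.201 in transplanted mice and 0.133 in controls), and the labels give no preparation batch. A change that followed the transplant itself stays open and untested.

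Chance was set against each count of genes by 100 splits of the same libraries, the real one included. For host against control, donor against control, donor against host and stroma, 1 of 100 splits gave as many genes, the real one, which argues against chance at that number of splits. These splits ignored the day of euthanasia and the animal, which libraries shared. The real counts were 2312, 6360, 1928 and 391, and the highest of the other splits 1131, 4957, 1845 and 42. The median of the other splits was 0 in all 4, and 3, 3, 4 and 7 of them gave more than 0 genes. The highest ones lay near the real grouping. For host, 1 side held 6 of the 7 host libraries, and for donor against control the 7 donor libraries stayed together. For donor against host 1 side held 1 donor library beside host libraries, and for stroma 1 transplanted library beside controls. Exchanging donor and host labels within animals, 1 of 64 splits gave as many as 1928, with 549 the highest other. For the CD11b cells all 10 splits gave at least the real count of 0, with 3 the highest other, and 10 splits are too few for a share below 0.05.

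Among 78 groups tested for a library far from the others, 13 had one, and chance alone gives about 1 in 20, or 3.9. Host library N269 had 20468 genes detected, with 21056 the nearest of the others. Donor library N032 had 0.0147% of counts in haemoglobin genes, with 0.0069% next. Control library N051 had 1.54% in mitochondrial genes, with 1.16% next, and 6.61% in ribosomal protein genes, with 4.99% next. Stroma control N002 had 143.23 M counts, with 64.51 M next, and stroma library N032 of a transplanted mouse 6.99% in ribosomal protein genes, with 3.29% next. Vcan was at 34.4 CPM in control N093 (next 23.0), Saa3 at 23.3 CPM in host N005 (next 14.2), Pklr at 1.77 CPM in control N288 (next 0.933) and Ms4a1 at 1.68 CPM in donor N203 (next 0.644). In stroma, Tcrg-C1 was at 70.0 CPM in N032 (next 12.1), Alas2 at 514.3 CPM in N203 (next 248.5), both transplanted, and Cxcl12 at 6235 CPM in control N208 (next 3278).

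For 21 genes host and donor cells were called on opposite sides of the same controls, and donor against host values of genes so chosen restate that choice. These log2 values by edgeR were Pklr 5.49, Car1 4.96, Gm15915 3.80, Atp1b2 3.72, Myh10 3.51, Ces2g 2.84, Aqp1 2.34, Abcb4 2.22, Reps2 1.68, Nfia 1.21, Mns1 1.00, Blvrb 0.67 and C1qtnf12 0.58 for the 13 genes lower in host and higher in donor cells than in controls, and Gzmk -5.04, Fabp4 -3.35, Pdcd1 -2.64, Pparg -2.48, Acp5 -1.35, Itgax -1.24, Adgre4 -1.06 and Bend4 -0.72 for the 8 in the other direction.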

How the results depend on the processing

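Alternatives with N032 and N093 left out, the GC trend removed, N269 and N280 left out, and the second CD11b day alone were chosen after seeing the data; all others were planned. No named gene that passed changed direction under any alternative, nor did any list that passed in both the main test and the alternative. Of the named genes that passed, 19 of 125 in host, 76 of 171 in donor, 50 of 120 in donor against host and 0 of 52 in stroma did so under every alternative, each sex alone included. The stroma value was fixed by females alone, where edgeR called 0 genes and all 52 were lost. Males alone lost 30 of the 52, and every other stroma alternative at most 13. In host cells females alone lost 102 and the fold minimum 84. Where values moved, the cause was not tested, except that each sex alone and left-out libraries hold fewer samples and a fold minimum counts fewer genes.

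Host against control gave 2312 genes, 286 at a log2 of at least 1, 719 on TPM plus 1, 736 on TPM plus 0.1, 1155 at a mean TPM of 1, 479 in males, 121 in females, 2195 without the N269 and N280 libraries, and 1527 (without N014) to 2687 (without N203) leaving out 1 library. Donor against control gave 6360, 1226 at a log2 of at least 1, 3027 in males, and 5730 to 6732 leaving out 1 library. Donor against host gave 1928, 696 at a log2 of at least 1, 1190, 1250 and 1036 on the 3 TPM settings, 1136 in males, 450 in females, 1507 to 2554 leaving out 1 library, 4605 with the animal as a block and 4504 as a random effect. Stroma gave 391, 741 with DESeq2, 705 with voom and quality weights, 125 in males, 0 in females (edgeR, 1365 at an unadjusted p below 0.05), 250 with the day as a block, 272 (without N002) to 593 (without N032), 478 without N032 and N093 and 313 with the GC trend removed. With the day as a block 10 of the 22 genes shared by host, donor and stroma passed in all 3 (7 of 11 higher, 3 of 11 lower), while the counts of host, donor and CD11b cells against controls changed by no more than 1.5 times. CD11b gave 0 with edgeR (2506 at an unadjusted p below 0.05), 333 with DESeq2, 0 with voom, 59 without a filter, 1 on TPM plus 0.1 and 1 at a mean TPM of 1 (Gm37419 in both, chosen after its values were seen; all genes shifted by a median log2 of 0.13 and 0.12), 7 on the second day alone, and 0 to 28 leaving out 1 library (28 without N187; 3 without N129, Amer2, Cadm1 and Saa3).

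Gene lists that passed numbered 18 in host (1 with an estimated correlation, 11 by fry), 15 in donor (0 and 25), 20 in donor against host (0 with an estimated correlation), 13 in stroma (0, 0 by fry, 20 with the day as a block) and 15 in CD11b cells (0 and 0). The sex interaction gave 0 with edgeR in host cells, 2 without a filter (Hspa1a, Ighg3) and 0 to 2 leaving out 1 library (2 without N279, Fcrl5 and Pltp), and in stroma 0, and 0 to 5 leaving out 1 library (5 without N014: Cebpd, Lamp1, Mgat2, Sumf1, Syap1). Chimerism slopes gave 0 with edgeR, and in host cells 3 with DESeq2 (Ace, Igkv1-122, Il13) and 3 without a filter (Igkv1-122, Il13, Usp26), in donor cells 19 without a filter, and in stroma 17 with DESeq2 and 4 without a filter (Aoc1, Ighv1-53, Krt19, Krt8), and 0 leaving out any 1 library. Genes of these small counts were chosen after their values were seen. The host and donor overlap of 2052 was 787 with split controls, host and CD11b r was 0.621 at a mean log2 CPM of at least 4, and host and stroma r turned from 0.0735 to -0.052 there.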

Other observations

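The genes and the test of same-animal levels in this part were chosen after the values were seen; the split test of the host and CD11b correlation was written before its result.

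Of the 21 genes that moved in opposite directions in host and donor cells, 8 rose in host and fell in donor cells, and no list or test joins them. Fabp4, a fatty-acid binding protein gene, was at a log2 of 2.34 in host and -0.98 in donor cells, and Pparg, the nuclear receptor that drives it, at 0.90 and -1.58 (edgeR adjusted p = 0.00967 and 7.65e-04). Acp5, the tartrate-resistant phosphatase of osteoclasts, was at 0.70 and -0.65, and Itgax, which encodes CD11c, at 0.53 and -0.71. Gzmk, a granzyme gene of lymphocytes, was at 1.09 and -3.93, Pdcd1, which encodes PD-1, at 0.95 and -1.65, Adgre4 at 0.55 and -0.52, and Bend4 at 0.36 and -0.36. Fabp4 did not pass in donor cells with the day of euthanasia as a block, on TPM or in either sex alone. Pparg did not pass in host cells of females alone or in donor cells of males alone.

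Among mitochondrially encoded genes mt-Nd3 stood apart, with a log2 of -3.05 in donor cells against controls (edgeR adjusted p = 9.33e-07) and -2.78 against host cells (edgeR adjusted p = 1.83e-05), at a mean of 0.202 CPM in donor cells and 1.67 in controls. On TPM plus 1 the difference from host cells was -0.30 and did not pass. Of 20 immediate-early and heat-shock genes 5 fell in host cells (7 adjusted over the list alone; camera adjusted p = 0.00114, adjusted p = 0.565 with an estimated correlation), among them Nr4a1 at -0.38, which did not pass in either sex alone, and Btg2 at -0.54, and 11 fell in donor cells (also adjusted over the list alone; camera adjusted p = 0.00189, adjusted p = 0.447 with an estimated correlation).

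A hypothesis was that host and donor cells of 1 animal share the level of genes that rose in both, tested on Vcan, Saa3 and Lipg across the 7 animals with exact two-sided permutation tests adjusted over the 3 genes. Vcan gave Pearson r = 0.848 (exact p = 0.00774, adjusted 0.0208) and Spearman rho = 0.929 (exact p = 0.00675, adjusted 0.0101), and r = 0.822 without the 2 animals farthest from the median and 0.726 centred by sex. Saa3 gave r = 0.920 (exact p = 0.0139, adjusted 0.0208) and rho = 0.964 (exact p = 0.00278, adjusted 0.00833), and r = 0.635 without the 2 farthest animals and 0.902 centred by sex. Lipg gave r = 0.547 (exact p = 0.207, adjusted 0.207) and rho = 0.25 (exact p = 0.595, adjusted 0.595), and r = -0.37 without the 2 farthest and 0.768 centred by sex. The hypothesis asked for all 3 genes and so was not borne out as stated. Host and donor libraries of 1 animal deviated together across genes in all 7 animals (r of 0.174 to 0.6), and no other genes were tested as a baseline. A shared level may hold for Vcan and Saa3, but it was not separated from that general likeness. A shared day or handling of each animal was not separated from it either.

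The correlation across genes of 0.417 between host and CD11b changes was as large in 1 of 10 splits of the CD11b libraries, the real one, with 0.388 the highest of the others, and 10 splits are too few for a share below 0.05.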
